A study of Mus musculus with 36 samples.

How the data were processed

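RNA from the skin of 36 mice was labelled with Cy3 and hybridised to 36 single-colour Agilent arrays, 1 per mouse, in 4 groups of 9 (4 males and 5 females each), per the labels. Skin was collected 24 h after treatment with an argon plasma jet at 0, 3 or 20 s/mm², or from controls, per the labels' protocols. The scanner files hold intensity values made with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed signal is the spot's intensity after background subtraction and detrending within the array, with no scaling between arrays, per the file headers. The median signal and the local background median are uncorrected pixel intensities, and 0 or 1 marks record whether a spot was well above background, saturated or an outlier, per the file headers. The authors' series matrix holds the processed signal, since all its values (100%) equalled the scanner values to rounding. The authors also deposited a table of normalized values, which is on a log2 scale as judged against the scanner values. Its slopes on the log2 scanner values of the same array were 0.83 to 0.96, the correlations across probes 0.919 to 0.966, and 36 of 36 columns lay closest to their own array. It is centred per probe, with a median over its columns of 0, and its column medians run from −1.45 to 1.33; how it was normalized is not stated. Of its 38023 probes, 37885 matched the array, and the table served only as an alternative.

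Control spots were left out, spots marked as outliers were set aside, and spots of one probe were averaged, which gave 55761 probes from 58986 of 62657 spots. The arrays' annotation and the reference table of gene names, which is of another build (GRCm38.p6, against mm9 in the file headers), were used for names only. An accession gave a gene symbol to 27656 probes, with 20972 distinct symbols, and 28105 probes kept the accession or identifier of the array design. Values were log2 of the processed signal minus each array's 75th percentile. Because fewer than 50% of the probes were well above background on most arrays, the percentile was taken over the 6842 probes well above background on all 36 arrays, with all probes as an alternative. A probe was kept if it was well above background on at least 7 of the 9 arrays of a group (20924 probes). Each gene was represented by the kept probe of highest mean, which left 16923 genes, 11520 of them with a symbol. Array brightness was the same percentile, and 7 of 10 spike-in probes gave the brightness of control RNA.

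Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the files read by the package data.table in its version 1.17.8, over all 36 arrays with terms for group and sex. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05, and SE is limma's moderated standard error. The 6 comparisons between groups, the difference between the sexes and the interactions of sex with 3 and 20 s/mm² were tested. Sex-linked genes were fitted without the filter on dim probes. The comparisons, 48 gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The 47 lists with at least 5 genes measured that are not of sex-linked genes were tested with camera with a preset correlation of 0.01. Splits of the arrays that mixed the groups passed a median of 6 to 11 lists in this test, so its adjusted p-values are too small here. Of 1436 list genes with a symbol, 1404 were on the array. The number of genes past the threshold is also given adjusted over the list alone. For these set tests 211 of 609228 values were filled with the mean of the group and sex. Array brightness was compared with exact two-sided permutation tests over all 48620 splits of 18 arrays into 9 and 9, adjusted over 18 tests. These splits do not keep the slides.

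Genes were named by a rule. Past the threshold, of the same sign in males and females and with an official-style symbol, it took the 10 largest rises and 10 largest falls for each exposure against controls, and 5 and 5 for the other comparisons. For each list past its test or with at least 2 genes called, it took at most 4 called genes with the largest change, or 2 of smallest p given as values only. The text gives 1 to 4 of these for most lists. Where no gene passed, the 5 of smallest p are given (3 for the interactions). A gene well above background on at most 4 of the 9 arrays of a group has only a bound there, and the number 4 was chosen after seeing the data. Folds given as "at least" compare the brighter group's mean with the mean, over the dimmer group's arrays, of the higher of the gene's own value and the lowest value among probes well above background. Slides (5) and scan days (3) are in the file headers. Slide was fitted as a block and the comparisons were repeated within each of the 4 slides of 8 arrays, while the slide of 4 arrays has 1 array per group and no test. Every slide held equal numbers of arrays of each group, so the block alters the spread of a change between groups and hardly its size. Scan days each held whole slides, so the slide block covers them.

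The alternatives fixed in advance were normexp background correction (offset 50, on the median signal, since the files lack the mean signal that had been planned), quantile normalization, no filter on dim probes, only probes well above background on all 36 arrays, each probe on its own, no term for sex, a block for the replicate number, a block for slide and array weights. They further included only the 2 groups compared, each sex alone, the deposited values, leaving out each array in turn, camera with an estimated correlation and fry. Fry asks whether the genes of a list changed at all, and camera whether they changed more than other genes. The percentile over all probes, the array signal as a covariate, slide and array signal together, leaving out the 8 arrays of the dimmest slide, and leaving out the 2 libraries at odds with their sex label were chosen after seeing the data. The fit was tested on simulated data for the 20 s group against controls, with 200 of 16923 genes changed. It recovered 1.49% of genes changed 1.5-fold, 17.9% changed 2-fold and 56.1% changed 4-fold, called 5 unchanged genes, and called the 1 list that was shifted. The simulated noise was independent between genes and between arrays, with no effect of slide or array signal. The simulation therefore does not show how the fit or the list test behaves on the real arrays, which share slides and differ in signal. Brightness over background sets what can be seen: between 20.4% and 66.3% of probes were well above background on an array. No array was left out, and no 2 arrays were copies.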

Results

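Skin was taken 24 h after exposure to an argon plasma jet, a device that ionises a stream of argon at atmospheric pressure, and its RNA was measured on 36 single-colour arrays. The 4 groups of 9 mice were controls labelled as non-treated, mice recorded as given 0 s/mm² of plasma, and mice given 3 or 20 s/mm² (the 0 s, 3 s and 20 s groups). Each group held 4 males and 5 females by label. The labels do not say how the 0 s mice differed from the controls. The series title speaks of healthy skin, while the protocols also mention wounds and tissue from ears, so the site and state of the skin are not settled. The arrays lay on 5 slides, of which 4 held 2 arrays of each group and 1 held 1 array of each. Arrays are measured by brightness, and the number of arrays limits the precision of every value.

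Arrays from plasma-treated skin were brighter than the others. The 75th percentile of the log2 signal of skin RNA was 9.40 ± 1.42 in controls (mean ± SD, n = 9), 9.37 ± 1.36 in the 0 s group, 10.99 ± 1.60 in the 3 s group and 11.24 ± 1.53 in the 20 s group. The 20 s arrays were 3.59-fold brighter than the control arrays (exact permutation test, two-sided p = 0.019, 0.058 after adjustment over 18 such tests) and brighter in 5 of 5 slides. The 3 s arrays were 3.02-fold brighter (exact p = 0.042, adjusted 0.093), also in 5 of 5 slides. The 0 s and control arrays differed by −0.03 log2 units (exact p = 0.96). Spike-in probes, which measure control RNA that does not come from skin, read 12.03 ± 2.11 in controls, 11.81 ± 1.89 in the 0 s group, 11.86 ± 1.85 in the 3 s group and 11.70 ± 2.02 in the 20 s group (SD, n = 9). The 20 s minus control difference was −0.33 (exact p = 0.72), and the 20 s arrays read lower in 5 of 5 slides. The permutations exchange arrays across slides, whose spike-ins averaged 8.55 to 13.33, so the p-values include the spread between slides. Within slides the 20 s minus control difference was −0.36 ± 0.10 for spike-ins and 1.82 ± 0.33 for skin signal (mean ± SE over 5 slides). Relative to the spike-ins of the same array, skin signal was 2.18 log2 units higher in the 20 s group than in controls (exact p = 0.0072, adjusted 0.043) and 1.77 higher in the 3 s group (exact p = 0.019, adjusted 0.058). The protocol gives the same mass of RNA for labelling in every sample, but not how much labelled RNA went onto each array, nor when the spike-ins were added. Between 20.4% and 66.3% of the probes of an array were well above background, on average 37.1 ± 14.9% in controls, 34.7 ± 11.2% in the 0 s group, 42.5 ± 8.49% in the 3 s group and 45.1 ± 11.7% in the 20 s group.

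**Figure D1:**
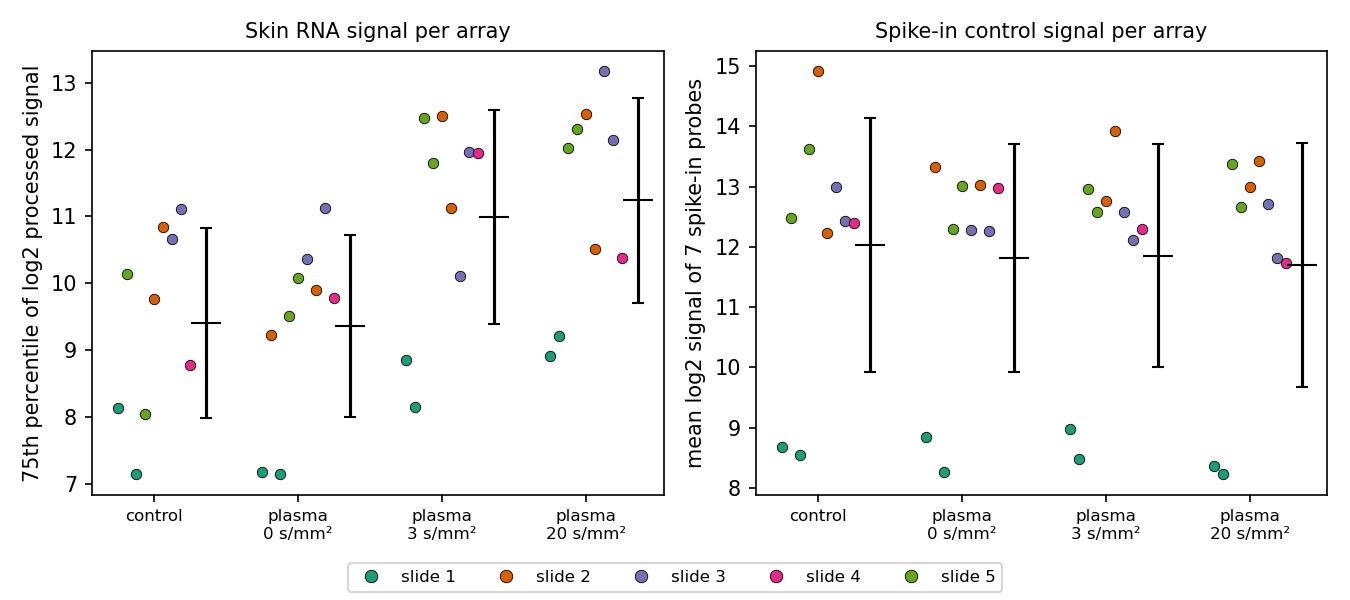
Signal of skin RNA (left, 75th percentile of the log2 processed signal) and of 7 spike-in probes (right, mean log2 signal) for each of the 36 arrays, by group and coloured by slide, with bars for the mean ± SD (n = 9). Skin signal averaged 9.40 in controls and 11.24 in the 20 s group, while the spike-ins averaged 12.03 and 11.70.

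Genes of the X and Y chromosomes served as a check of the labels. Arrays labelled female read lower than those labelled male for the Y-linked genes Ddx3y (log2 −5.32 ± 0.56 SE, adjusted p = 7.3e-07) and Eif2s3y (−3.15 ± 0.48, 1.0e-04), the latter well above background on 6 of 16 male and 1 of 20 female arrays. The other 2 Y-linked genes could not serve, since Uty was well above background on 0 male arrays and 1 female array and Kdm5d on none. Xist, the RNA that silences an X chromosome in female cells, read 2.78 ± 0.57 higher in females (adjusted p = 0.0010). Ddx3y was well above background on 14 of 16 male and 1 of 20 female arrays, and Xist on 1 of 16 male and 16 of 20 female arrays. The libraries labelled plasma_0s replicate 2 (male) and plasma_0s replicate 5 (female) stood against their labels. Replicate 2 had Xist well above background and not Ddx3y, and replicate 5 had Ddx3y well above background and not Xist. Over all genes, 6675 of 16923 differed between females and males (3555 higher and 3120 lower in females), but sex nearly coincided with slide. Of the 5 slides 3 held 1 sex, and the other 2 held 7 females with plasma_0s replicate 2 and 7 males with plasma_0s replicate 5. With slide as a block limma called 0 genes (1723 at an unadjusted p under 0.05), but that fit rests on these 2 libraries at odds with their labels and does not test the sexes. The sexes and the slides cannot be told apart here. The split was 1119 higher and 11214 lower under the normexp background correction, 4594 and 2321 under quantile normalization, 4596 and 2133 with the percentile over all probes, and 3780 and 2251 in the deposited values.

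The comparison of the 20 s group with controls asks what the longer exposure changed in skin 24 h later (n = 9 per group). Genes of mast cells, the histamine-storing cells of the skin, gave the largest rise of a gene group. Cpa3, a protease of mast cell granules, rose 7.47-fold (log2 2.90 ± 0.56 SE, adjusted p = 0.0013) and Kit, the receptor for stem cell factor, at least 2.92-fold (adjusted p = 0.0014). Hdc, the enzyme that makes histamine, rose at least 3.33-fold (0.0012) and Gata2, a transcription factor of that lineage, at least 2.47-fold (0.0011). All 4 were well above background on 9 of 9 plasma arrays, but on only 6, 3, 4 and 4 of the 9 control arrays in that order. Of the 10 measured genes on the mast cell and eosinophil list, 7 rose and 0 fell (the same 7 and 0 adjusted over the list alone). The other 3 were Srgn, a granule proteoglycan (0.16 ± 0.35, 0.73), the tryptase Tpsb2 (−0.049 ± 0.51, 0.94) and Gata1 (adjusted p = 0.82). Gata1 was well above background on only 4 control arrays and has no exact value, and control replicate 4 read −0.38 for it where the other controls read −9.67 to −6.76. Of the 3 genes well above background on every control array, Srgn, Tpsb2 and the protease Mcpt4, only Mcpt4 rose (1.84 ± 0.38, 0.0017; 1.58 under the normexp correction). Tpsb2 read 0.94 in the deposited values (adjusted p = 0.066). The filter took in a gene well above background on at least 7 of the 9 arrays of a group. The 20 s arrays met this for Cpa3, Kit, Hdc, Gata2, Cma1 and Tpsg1 (8 or 9 arrays), and the controls did not (6, 3, 4, 4, 6 and 0 arrays). The filter thus favours rises in the count of 7 and 0. The list's median lay 1.48 above that of all genes (camera, adjusted p = 0.0037; adjusted p = 0.41 with an estimated correlation), between 0.90 and 1.80 above it in each of the 5 slides. It was still 0.30 above it under the normexp background correction, although the list's own median was −0.39 and only 1 of its genes rose there. Under that correction Cpa3 read 0.62 (limma's adjusted p = 0.15) and Hdc 0.10 (0.77), neither past the threshold, while Kit read −0.39 and Gata2 −0.40. With the array signal as a covariate the list stayed 1.28 above all genes, and Cpa3 (2.56) and Mcpt4 (2.02) stayed past the threshold. So did Kit, Hdc and Gata2 (adjusted p = 0.044, 0.047 and 0.036), whose size is not given because most control arrays were near background. Cma1 (1.25 without and 1.26 with it, adjusted p = 0.11) and Tpsg1 (adjusted p = 0.084), both called without the covariate, did not. Mcpt4, Srgn, Tpsb2, Gata1, Cma1 and Tpsg1, the last well above background on 0 control arrays, are named after their values were seen.

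**Figure D2:**
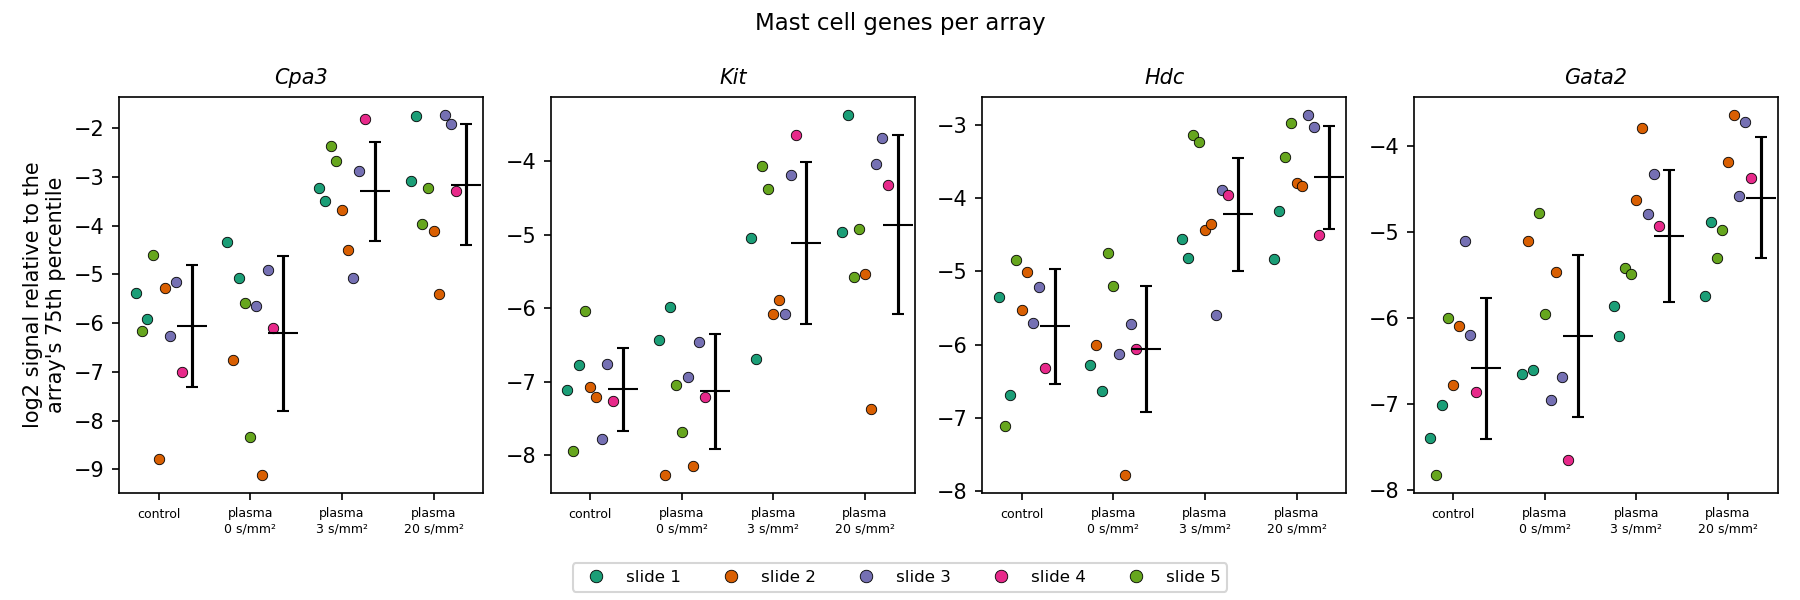
Log2 signal of the mast cell genes Cpa3, Kit, Hdc and Gata2 relative to each array's 75th percentile, for each array by group and coloured by slide, with bars for the mean ± SD (n = 9). In the 20 s group Cpa3 was 7.47-fold higher than in controls and the others at least 2.47-fold to 3.33-fold. Under the normexp background correction none of them passed the threshold: Cpa3 read 0.62 and Hdc 0.10 in log2 units, and Kit (−0.39) and Gata2 (−0.40) read lower than in controls.

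Lists of defence against oxidants and of the connective tissue also lay above all genes in the 20 s group. In what follows a list's place is its median relative to the median change of all genes, which was 0.21 in log2 units (−0.69 under the normexp correction, 0.35 under quantile normalization, 0.38 with the percentile over all probes). Each list past its test kept its side of that median under these scalings and in the deposited values. All genes include 5403 without a symbol, which no list holds, and camera compared with all genes too. Of genes with a symbol 7.39% were called lower, against 13.8% of all genes. A place above all genes may therefore be shared by the genes with a symbol as a whole, whose median was not taken. Targets of NRF2, the transcription factor of the oxidant response, lay 0.51 above all genes (19 of 39 rose and 0 fell, also adjusted over the list alone; adjusted p = 0.0014). Gclc, which makes the first step of glutathione synthesis, rose 3.04-fold (log2 1.60 ± 0.24 SE, adjusted p = 6.2e-04). Nqo1, a quinone reductase, rose at least 1.33-fold (adjusted p = 0.045; well above background on 7 plasma arrays and 1 control array), a call lost in 13 of the 18 fits that left out 1 array (highest adjusted p 0.094). Fibroblast genes lay 0.67 above (11 of 25 rose and 0 fell by either adjustment) and collagen and matrix genes 0.53 above (14 of 43 rose and 1 fell, 16 and 1 adjusted over the list alone; both adjusted p = 0.0037). Cilp, a matrix protein, rose 3.98-fold (1.99 ± 0.56, 0.010), Loxl1, an enzyme that crosslinks elastin, at least 2.74-fold (0.0069) and Vim, an intermediate filament protein, 2.98-fold (1.57 ± 0.36, 0.0031). Adipocyte genes lay 0.70 above (10 of 29 rose and 0 fell, 11 and 0 adjusted over the list alone; 0.0073), among them the fatty acid carrier Cd36 (1.98 ± 0.59, adjusted p = 0.013) and the lipase Lpl (1.78 ± 0.54, 0.014). Endothelial genes lay 0.84 above (8 of 19 rose and 1 fell, 11 and 1 adjusted over the list alone; 0.010). Tie1, a receptor of vessel walls, rose at least 1.44-fold (0.0039; well above background on 2 control arrays). The one endothelial gene that fell, Kdr, a receptor for vessel growth factor (−2.95 ± 0.63, 0.0022), had a second probe of opposite sign and read 0.73 in the deposited values. Each of these lists was above all genes in 5 of 5 slides, except matrix genes in 4 of 5, and each had an adjusted p of 0.41 with an estimated correlation.

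Lists of stress and growth genes lay above all genes as well. Immediate early genes, which respond first to a stimulus, lay 0.46 above all genes (7 of 24 rose and 0 fell by either adjustment). The transcription factors Egr1 and Egr2 rose 3.40-fold (log2 1.76 ± 0.39 SE, adjusted p = 0.0024) and 3.02-fold (1.60 ± 0.32, 0.0016). Genes of the glucocorticoid response lay 0.56 above (6 of 19 rose and 0 fell, 7 and 0 adjusted over the list alone). Errfi1 rose 2.97-fold (1.57 ± 0.42, 0.0069) and Cebpd 2.89-fold (1.53 ± 0.43, 0.011). Heat shock genes lay 0.39 above (8 of 25 rose and 0 fell, 9 and 0 adjusted over the list alone), with the cochaperone Fkbp4 3.03-fold higher (1.60 ± 0.50, 0.017). Proliferation genes lay 0.51 above (11 of 31 rose and 1 fell, 13 and 1 adjusted over the list alone). The replication helicase subunit Mcm3 rose 2.17-fold (1.12 ± 0.27, 0.0047), while Tyms, which makes thymidylate, fell 3.06-fold (−1.61 ± 0.51, 0.018; well above background on 7 plasma and 6 control arrays). These 4 lists had camera's adjusted p = 0.0037, were above all genes in 5 of 5 slides, and had an adjusted p of 0.41 with an estimated correlation. A further 10 lists lay between 0.13 and 0.75 above all genes. In 5 of them 0 genes fell: the unfolded protein response (8 of 22 rose), circadian clock (6 of 17), matrix proteases (8 of 21), apoptosis (7 of 25, 6 adjusted over the list alone) and oxidative phosphorylation (12 of 44). In the others 1 or 2 genes fell: growth factors (8 of 24 rose, 11 adjusted over the list alone), sebaceous gland (14 of 27), hypoxia (8 of 30), hair follicle stem cells (8 of 13, 9 adjusted over the list alone) and antioxidant enzymes (10 of 30). Where no second count is given, it was the same adjusted over the list alone. Their adjusted p was 0.0037 to 0.044. With an estimated correlation the adjusted p was 0.41, and 0.56 for oxidative phosphorylation, which lay on the other side of all genes (−0.10) with the array signal as a covariate.

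Lists of neutrophils, T and NK cells and B cells lay below all genes in the 20 s group. Neutrophil genes lay at −1.50 relative to all genes (4 of 12 fell and 0 rose, 6 and 0 adjusted over the list alone; adjusted p = 0.0061), with the integrin Itgam 7.50-fold lower (log2 −2.91 ± 0.60 SE, adjusted p = 0.0017). T and NK cell genes lay at −0.79 (5 of 16 fell and 0 rose by either adjustment; 0.0090), with the T cell receptor component Cd3e 3.60-fold lower (−1.85 ± 0.44, 0.0040). B cell genes lay at −1.69 (2 of 5 fell and 0 rose, 3 and 0 adjusted over the list alone; 0.0090). Cr2, a complement receptor, was 8.22-fold lower (−3.04 ± 0.74, 0.0044; well above background on 5 plasma and 6 control arrays) and Cd22 3.09-fold lower (−1.63 ± 0.44, 0.0081). All 3 lists were below all genes in 5 of 5 slides, and each had an adjusted p of 0.41 with an estimated correlation. Olfactory and vomeronasal receptor genes, which have no known use in skin and were chosen after the data were seen, lay lower still. They lay at −1.71 relative to all genes, so the falls of these lists do not by themselves show fewer of these cells. Genes of the cornified envelope, the protein shell of the outermost skin cells, lay at −0.78 (adjusted p = 0.0037; adjusted p = 0.56 with an estimated correlation), and below all genes in 4 of 5 slides. Of 40 such genes 1 passed, Sbsn (−0.71 ± 0.27, adjusted p = 0.040; lost in 10 of the 18 fits that left out 1 array), and 0 passed adjusted over the list alone.

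**Figure D3:**
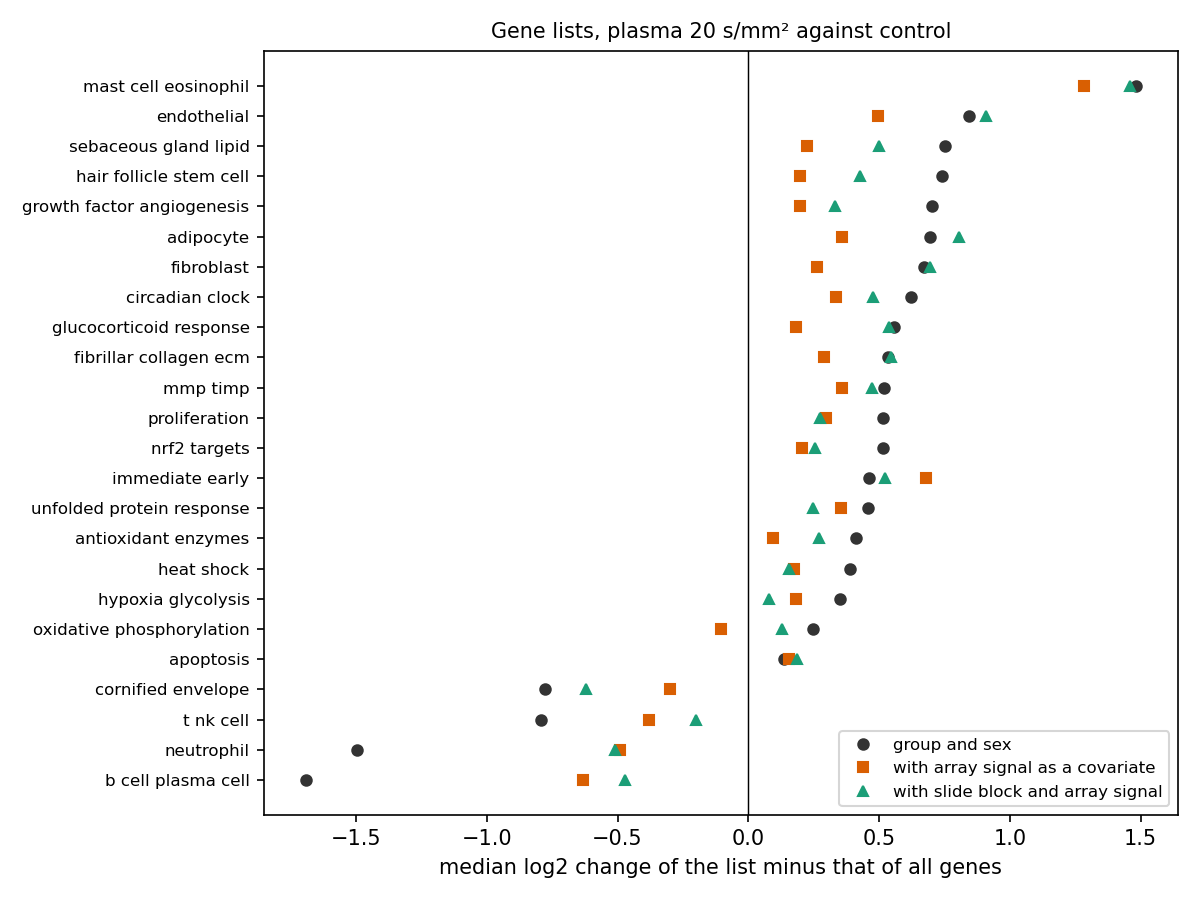
Median log2 change of each of the 24 gene lists past the threshold in the 20 s group against controls, minus the median of all genes, in the fit with group and sex (circles), with the array signal as a covariate (squares) and with slide block and array signal (triangles). The mast cell list stayed farthest above all genes (1.48, 1.28 and 1.46), oxidative phosphorylation went to the other side with the array signal (−0.10), and no list changed side under another scaling.

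Among single genes, the largest rises after Cpa3 included Lhx2, a transcription factor of the hair follicle, at least 3.25-fold (adjusted p = 2.3e-04), and Dct, an enzyme of melanin synthesis, 5.21-fold (log2 2.38 ± 0.46 SE, 0.0013). Next came Rab15 4.93-fold (2.30 ± 0.56, 0.0043) and Col6a3, a collagen, 4.90-fold (2.29 ± 0.50, 0.0022). Thrsp and Ces1d followed with 4.89-fold and 4.80-fold, and Glis2 and Zfp106 with at least 2.88-fold and 3.64-fold. Control arrays with these genes well above background numbered 3 to 7 of 9, against 8 or 9 of 9 in the 20 s group. Thrsp lost its call without plasma_20s replicate 7 (1.91, adjusted p = 0.055). Over all genes tested the largest fall was −4.87. Among the genes that the naming rule allows, the largest falls were Slc26a1, an anion transporter, 14.8-fold (−3.89 ± 0.89, 0.0030; well above background on 5 plasma arrays) and Tssk5, a testis kinase, 13.1-fold (−3.71 ± 0.72, 0.0013; 7 arrays). Atp2b2, a calcium pump, fell at least 11.2-fold (0.0021; 4 arrays). Pign fell 12.5-fold (−3.65 ± 0.67, 0.0012; 9 arrays). Wfdc13 (3 plasma and 8 control arrays) and Amer3 (4 and 5) were at least 7.96-fold and 6.24-fold lower. Fgf23, a bone hormone, Idua and Slc17a5, both of the lysosome, were 10.1-fold to 10.6-fold lower, and the second probes of Idua and Slc17a5 went the other way. Rsph4a, a part of cilia, was well above background on 7 control arrays and 0 plasma arrays, at least 5.95-fold lower (adjusted p = 0.0016).

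In all, 5216 of 16923 genes (30.8%) passed the threshold, 2889 higher and 2327 lower (2575 and 851 among the 3426 with a symbol). The split depended on the scaling: 428 higher and 7171 lower under the normexp correction, where Glis2 (−0.037), Loxl1 (−0.28), Tie1 (−0.81), Mcm3 (−0.12), Fkbp4 (−0.46) and Nqo1 (−0.85) turned below 0, and 3641 and 2020 under quantile normalization. Without the filter on dim probes it was 3278 higher and 16138 lower, with a median of all genes of −1.09, and without the dimmest slide 1895 and 2811. With slide as a block 8343 genes passed, and within the 4 slides of 2 arrays per group 0, 0, 0 and 3503 did (4743, 1468, 4884 and 6453 at an unadjusted p under 0.05). Of the 46 genes chosen by rule for this comparison, 41 changed the same way in each of the 5 slides, and all 46 passed with the block. Each slide holds equal numbers of arrays of every group, so the block leaves the changes as they were (largest shift 0) and alters only their spread. All 24 lists past camera's test kept their call with the block, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) and 32 passed fry's directional test. With the array signal as a covariate 231 genes passed, 203 of them among the 5216, and 13 of the 24 lists. With slide block and array signal together 19 of the 24 lists passed and 2 genes, both among the 5216. They were Gata2 (adjusted p = 0.020; 4 control arrays well above background, so no exact value) and Wfdc21 (log2 −2.31 ± 0.42 SE), the latter named after its values were seen.

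The comparison of the 3 s group with controls asks what the shorter exposure changed (n = 9 per group). Mast cell genes again gave the largest rise of a group. Cpa3 rose 6.78-fold (log2 2.76 ± 0.56 SE, adjusted p = 0.0030), Kit at least 2.45-fold (0.0036) and Mcpt-ps1, a mast cell protease pseudogene, at least 2.59-fold (0.0029). They were well above background on 6, 3 and 4 control arrays and on 9, 8 and 9 plasma arrays. Under the normexp correction Cpa3 read 0.60 and did not pass (limma's adjusted p = 0.16). Of the 10 mast cell genes measured 5 rose and 0 fell (7 and 0 adjusted over the list alone). The list's median lay 1.22 above that of all genes and 0.32 above it under the normexp correction, where its own median was −0.35. The median of all genes was 0.15 (−0.67 under the normexp correction, 0.33 under quantile normalization, 0.42 with the percentile over all probes), and lists are placed relative to it. Each list past its test kept its side under these scalings and in the deposited values, except apoptosis and oxidative phosphorylation under quantile normalization. Here too the lists hold only genes with a symbol. Of these 1607 were called higher and 725 lower, against 1762 and 2044 of all genes. Part of a place above all genes may thus belong to the genes with a symbol as a whole. Proliferation genes lay 0.55 above (11 of 31 rose and 1 fell, 19 and 1 adjusted over the list alone; adjusted p = 4.9e-05), with Mcm3 2.59-fold higher (1.38 ± 0.27, 0.0029). NRF2 targets lay 0.49 above (12 of 39 rose and 0 fell, 13 and 0 adjusted over the list alone; 6.1e-04). Pgd, which makes NADPH, rose 2.25-fold (1.17 ± 0.26, 0.0036) and the exporter Abcc4 at least 1.84-fold (0.014; 4 control arrays). Genes of the glucocorticoid response lay 0.59 above (6 of 19 rose, 9 adjusted over the list alone) and heat shock genes 0.50 above (7 of 25 rose, 11 adjusted over the list alone). Immediate early genes lay 0.45 above (5 of 24 rose) and the unfolded protein response 0.49 above (5 of 22 rose), the same by either adjustment, with 0 falls in these 4 lists. Egr1 was 3.43-fold higher (1.78 ± 0.39, 0.0034). Each of these lists was above all genes in 5 of 5 slides, and camera's adjusted p was 0.0077 or less (adjusted p = 0.42 with an estimated correlation).

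Fibroblast, matrix, hair follicle stem cell and basal keratinocyte lists were also higher in the 3 s group. Fibroblast genes lay 0.43 above all genes (5 of 25 rose, 3 adjusted over the list alone; adjusted p = 0.0077). Matrix genes lay 0.47 above (10 of 43 rose and 1 fell by either adjustment; 0.013). Both were above all genes in 5 of 5 slides (adjusted p = 0.54 and 0.57 with an estimated correlation). Vim rose 2.51-fold (log2 1.33 ± 0.36 SE, adjusted p = 0.011), and Pdgfra, the receptor alpha of platelet-derived growth factor, at least 1.44-fold (0.021; 8 plasma and 4 control arrays), which lost its call without plasma_3s replicate 9 (1.02, adjusted p = 0.052). Hair follicle stem cell genes lay 0.99 above (5 of 13 rose and 2 fell, 7 and 2 adjusted over the list alone; 0.029, or adjusted p = 0.42 with an estimated correlation). Krt15, a keratin of follicle stem cells, was 2.50-fold higher (1.32 ± 0.32, 0.0057). The basal keratinocyte list lay 0.37 above (4 of 15 rose and 0 fell, 7 and 1 adjusted over the list alone; 0.029, or adjusted p = 0.43 with an estimated correlation). Sebaceous gland (0.69), hypoxia (0.34), cholesterol synthesis (0.35), apoptosis (0.20) and oxidative phosphorylation (0.18) lists were above all genes too, with camera's adjusted p of 0.029 to 0.049 (adjusted p = 0.42 to 0.74 with an estimated correlation). In that order 5 of 27, 4 of 30, 1 of 22, 6 of 25 and 1 of 44 of their genes rose (5, 2, 1, 6 and 0 adjusted over the list alone), and 1 sebaceous gland gene fell. Neutrophil genes lay at −1.30 (4 of 12 fell, 7 adjusted over the list alone; 0.0076, or adjusted p = 0.42 with an estimated correlation), in 5 of 5 slides, with Itgam 6.69-fold lower (−2.74 ± 0.60, 0.0034). B cell genes lay at −1.31 (2 of 5 fell by either adjustment; 0.019) and T and NK cell genes at −0.67 (3 of 16 fell, 4 adjusted over the list alone; 0.029). With an estimated correlation their adjusted p was 0.42 and 0.48. Cd3e was 3.32-fold lower (−1.73 ± 0.44, 0.0080). Olfactory and vomeronasal receptor genes lay lower than these lists here too, at −1.58 relative to all genes, so fewer of these cells cannot be read from the lists alone. Skeletal muscle genes lay at −0.81 (3 of 49 fell, 0 adjusted over the list alone; 0.013, or adjusted p = 0.74 with an estimated correlation), between −1.72 and 1.25 in single slides.

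Further large rises in the 3 s group were Ttyh3 4.11-fold (log2 2.04 ± 0.39 SE, adjusted p = 0.0029) and Dct 3.78-fold (1.92 ± 0.46, 0.0057). Rab15 and Soga1 were 3.67-fold and 3.60-fold higher, and Lhx2 and Glis2 at least 2.19-fold and 2.20-fold. Rab15 lost its call without plasma_3s replicate 3 (1.60, adjusted p = 0.052) and without plasma_3s replicate 4 (1.64, adjusted p = 0.05001). Soga1 read −0.21 in the deposited values. Slc4a7, a bicarbonate transporter, read 6.89-fold higher (2.79 ± 1.03, 0.048), but its second probe went the other way and the call was lost in 13 of the 18 fits that left out 1 array (2.06 without plasma_3s replicate 4, 2.07 without plasma_3s replicate 3 and 3.41 without plasma_3s replicate 1). Among the genes that the naming rule allows, large falls were those of Dvl3, a Wnt signalling protein, 10.9-fold (−3.45 ± 0.70, 0.0030), Krtap19-4, a hair protein, 10.6-fold (−3.41 ± 0.65, 0.0029), and Cyp17a1, an enzyme of steroid synthesis, 9.47-fold (−3.24 ± 0.69, 0.0032). Over all genes tested the largest fall was −4.53. Lepr, the leptin receptor, fell 9.35-fold (−3.22 ± 0.69, 0.0033) and Pign 9.31-fold (−3.22 ± 0.67, 0.0032). Idua was 9.41-fold lower with its second probe of opposite sign. Fam13c and Wfdc13 were 10.9-fold and 9.93-fold lower, well above background on 7 and 5 plasma arrays, and Atp2b2 and Acot3 at least 8.79-fold and 6.81-fold (3 and 2 arrays). Fam13c lost its call in 4 and Wfdc13 in 5 of 18 fits that left out 1 array, and Fam13c went from −3.44 to −2.66 without plasma_3s replicate 3 and to −2.71 without plasma_3s replicate 4.

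In all, 3806 of 16923 genes (22.5%) passed in the 3 s group, 1762 higher and 2044 lower (1607 and 725 among the 2332 with a symbol). The split was 310 and 5994 under the normexp correction, where Ttyh3 (−0.048), Kit (−0.26), Mcpt-ps1 (−0.23), Glis2 (−0.14), Lhx2 (−0.039), Abcc4 (−0.54) and Pdgfra (−0.52) turned below 0, 2508 and 1505 under quantile normalization, and 3216 and 1853 with the percentile over all probes. It was 2153 higher and 15484 lower without the filter on dim probes, with a median of all genes of −1.13, and 1145 and 2785 without the dimmest slide. The count was 2355 without control replicate 3, 2435 without control replicate 9, 2039 without plasma_3s replicate 3 and 2087 without plasma_3s replicate 4. With slide as a block 7048 genes passed, and within the 4 larger slides 0, 0, 0 and 5208 did (3508, 1848, 504 and 7487 at an unadjusted p under 0.05). All 38 genes chosen by rule passed with the block, which shifted no change by more than 0.014, and 33 of them had the same sign in every slide. Of the 20 lists past camera's test all kept their call with the block, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) and fry's directional test called 27. With the array signal as a covariate 43 genes and 8 of the 20 lists passed, and oxidative phosphorylation went to the other side of all genes (−0.17). With slide block and array signal limma called 0 genes (2863 at an unadjusted p under 0.05) and 16 of the 20 lists passed.

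The 0 s group and the controls, neither of which received plasma by label, were compared as well (n = 9 per group). No single gene passed the threshold in limma's test (248 of 16923 had an unadjusted p under 0.05, where chance gives 846), with slide as a block (562) or within any of the 4 larger slides (400, 1691, 503 and 2491). A count below chance does not show that the 2 groups are alike. The main fit has no term for slide, so its spread includes the slides. Arrays of different groups had a median correlation of 0.52 on the same slide and −0.18 on other slides. The genes of smallest p were Rbp4, a vitamin A carrier (log2 1.69 ± 0.48 SE), Mettl16 (−0.67 ± 0.20), Serpinb6e, Ddx55 and Csta3, each with an adjusted p of 1.0. The last 3 were well above background on only 4, 4 and 2 arrays of 1 of the groups and have no exact value. Relative to the median of all genes, lists of hair follicle keratins (0.51, camera's adjusted p = 5.1e-13) and adipocytes (0.57, 1.8e-10) were higher, and cornified envelope (−0.40, 5.6e-09) and wound keratin and alarmin genes (−0.44, 1.3e-08) lower, under every scaling. With an estimated correlation their adjusted p was 0.56, 0.19, 0.59 and 0.19. No member of these lists passed, adjusted over all genes or over the list alone. The signs held in 4, 4, 3 and 4 of 5 slides. Of the 11 lists past camera's test, fry called 0 (1 at an unadjusted p under 0.05), and camera with an estimated correlation 0 (4 at an unadjusted p under 0.05). The mast cell list lay at −0.07 relative to all genes.

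Both exposures were also compared with the 0 s group (n = 9 per group), and the 2 comparisons share the 9 arrays of that group. In the 20 s group Cpa3 was 8.29-fold (log2 3.05 ± 0.56 SE, adjusted p = 4.4e-04), Hdc 5.07-fold (2.34 ± 0.37, 2.8e-04) and Gclc 3.59-fold higher (1.84 ± 0.24, 9.9e-05). Relative to the median of all genes (0.27), immediate early genes lay 0.69 above (13 of 24 rose), NRF2 targets 0.62 above (22 of 39 rose, 1 fell) and mast cell genes 1.42 above (7 of 10 rose), with the same counts adjusted over the list alone. Proliferation genes lay 0.52 above (16 of 31 rose and 1 fell, 17 and 1 adjusted over the list alone). These 4 lists had camera's adjusted p of 0.0067 to 0.0091 (adjusted p = 0.60 with an estimated correlation), in 5 of 5 slides and on the same side of all genes under every scaling. In the 3 s group Cpa3 was 7.52-fold (2.91 ± 0.56, 8.7e-04), Kit at least 2.42-fold (0.0017; 2 arrays of the 0 s group) and Abcc4 at least 2.20-fold higher (0.0020; 4 arrays). Relative to all genes (0.20), proliferation genes lay 0.62 above (16 of 31 rose and 1 fell, 20 and 1 adjusted over the list alone) and NRF2 targets 0.65 above (19 of 39 rose and 1 fell, 20 and 1 adjusted over the list alone). Immediate early genes lay 0.49 above (9 of 24 rose by either adjustment) and mast cell genes 1.20 above (7 of 10 rose by either). Their adjusted p was 4.3e-04 to 0.012 (adjusted p = 0.51 with an estimated correlation), also in 5 of 5 slides and under every scaling. The mast cell list's own median was −0.43 and −0.34 under the normexp correction in the 20 s and 3 s comparisons, where all genes had −0.69 and −0.67.

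Other large rises against the 0 s group were those of the protease inhibitor Serpinb6d, 6.38-fold in the 20 s group (log2 2.67 ± 0.68 SE, adjusted p = 0.0033) and 6.90-fold in the 3 s group (2.79 ± 0.68, 0.0034). They were followed by Col6a3 (6.14-fold), Glis2 (at least 3.00-fold) and B4galt5 (at least 3.13-fold) in the 20 s group, and Xdh, a purine oxidase (at least 3.02-fold), Eif3a (at least 3.18-fold) and Arhgef4 (at least 3.03-fold) in the 3 s group. Under the normexp correction Glis2 (−0.037), B4galt5 (−0.20), Xdh (−0.20), Eif3a (−0.21), Kit (−0.30) and Abcc4 (−0.48) turned below 0. Falls in the 20 s group included Slc26a1, 18.1-fold (−4.18 ± 0.89, 0.0010), and Slc35e2, 14.1-fold (−3.82 ± 0.63, 2.8e-04), well above background on 5 and 9 of the 20 s arrays. Oxct2b was at least 8.27-fold lower (0.0014) and Kif12 at least 9.35-fold (0.0010), each well above background on 1 of the 20 s arrays. Rsph4a was at least 7.23-fold lower (well above background on 6 arrays of the 0 s group and 0 of the 20 s group). In the 3 s group Zfp790 fell 16.0-fold (−4.0 ± 1.27, 0.016) and Fam13c 13.3-fold (−3.73 ± 1.13, 0.013). Without plasma_3s replicate 3 Zfp790 read −3.36 and Fam13c −2.95, without plasma_3s replicate 4 −3.24 and −3.0, and without plasma_3s replicate 2 Zfp790 read −4.64. Krtap19-4 fell 13.2-fold (−3.72 ± 0.65, 6.7e-04), Dvl3 12.7-fold (−3.66 ± 0.70, 8.3e-04) and Oxct2b at least 6.47-fold (0.0046; 2 plasma arrays). Itgam was 8.98-fold (−3.17 ± 0.60, 5.1e-04) and 8.01-fold lower (−3.0 ± 0.60, 0.0010) in the 20 s and 3 s groups, and Csf3r, the receptor of a neutrophil growth factor, 3.91-fold and 3.98-fold lower. Skeletal muscle genes lay at −0.99 in the 3 s group (6 of 49 fell, 0 adjusted over the list alone; adjusted p = 0.0036, or adjusted p = 0.72 with an estimated correlation).

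Against the 0 s group 7322 genes passed in the 20 s group (4510 higher, 2812 lower, or 3903 and 1058 among those with a symbol) and 5997 in the 3 s group (3349 and 2648, or 2956 and 985 with a symbol). Under the normexp correction these splits were 694 and 7369, and 588 and 6547, and with the percentile over all probes the 3 s split was 4628 and 2424; under quantile normalization it was 3861 and 1965. Without the filter on dim probes the splits were 4678 and 16456, and 3541 and 16100. With slide as a block 10022 and 9026 genes passed. Within the 4 larger slides 0, 1 (Zfp790, −6.70 ± 0.58 SE), 0 and 4147 genes passed in the 20 s group (4937, 4488, 4830 and 7074 at an unadjusted p under 0.05). In the 3 s group 0, 338, 0 and 6553 did (4241, 4693, 663 and 8481 at an unadjusted p under 0.05). Camera called 13 and 12 lists, all of them also with the block and none with an estimated correlation (0 at an unadjusted p under 0.05 in either), and fry called 32 and 28. With the array signal as a covariate 2173 and 1775 genes passed, of which 1775 and 1543 had passed without it, and 3 of the 13 and 8 of the 12 lists. Oxidative phosphorylation went from 0.22 above all genes in the 20 s group to −0.20. With slide block and array signal, limma called 0 genes (2995 at an unadjusted p under 0.05) and 174 genes.

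The 20 s and 3 s groups were compared to see what the longer exposure added (n = 9 per group). No single gene passed in limma's test (107 of 16923 at an unadjusted p under 0.05), with slide as a block (322), or within 3 of the 4 larger slides. Within the last 6 genes passed (521, 37, 2180 and 1255 at an unadjusted p under 0.05 in the 4 slides). Here too the spread of the main fit includes the slides, so its low count does not show that the 2 groups are alike. The genes of smallest p were Mylk, a kinase of smooth muscle (log2 1.04 ± 0.29 SE), Plcl1 (1.20 ± 0.35), Tlcd3b (1.00 ± 0.30), Fzd4 (1.17 ± 0.36) and Car3, an enzyme abundant in fat and muscle (1.22 ± 0.38), each with an adjusted p of 1.0. Relative to all genes, cornified envelope genes were lower in the 20 s group (−0.53, camera's adjusted p = 3.1e-21) and in 5 of 5 slides, with Cdsn, a protein of corneocyte junctions, at −0.58 ± 0.27 and Sprr1b at −0.60 ± 0.30. Skeletal muscle genes were higher (0.74, 2.0e-13), with Neb at 1.30 ± 0.62, in 4 of 5 slides, as were endothelial genes (0.30, 1.0e-05), with Ptprb at 0.76 ± 0.34 and Tie1 at 0.71 ± 0.43. All 3 lists kept their side under every scaling, no member passed, adjusted over all genes or over the list alone, and with an estimated correlation their adjusted p was 0.27, 0.49 and 0.27. Of the 14 lists past camera's test, 0 passed with an estimated correlation (5 at an unadjusted p under 0.05), and fry called 0 (0 at an unadjusted p under 0.05).

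Whether males and females responded differently was tested as an interaction. No gene passed the threshold for a different response, at 3 s/mm² (522 of 16923 at an unadjusted p under 0.05, where chance gives 846) or at 20 s/mm² (418), in limma's test, nor with slide as a block (1143 and 1067). This does not show that the sexes responded alike. In the control, 3 s and 20 s groups no slide held both sexes, so a response that differs by slide cannot be told apart from one that differs by sex. With array weights 2744 and 162 genes passed. The genes of smallest p at 3 s/mm² were Tmem39b, with a female minus male difference in log2 change of −1.82 ± 0.40 (SE), Zfp644 (−3.01 ± 0.77) and Csta3 (3.25 ± 0.84). At 20 s/mm² they were Unc93a (2.97 ± 0.75), Kif5c (2.21 ± 0.59) and Dbn1 (−2.10 ± 0.56). All had an adjusted p of 1.0. Fitted alone, the 4 males per group gave 0 genes for 20 s against control (3822 at an unadjusted p under 0.05) and 8 for 3 s. The 5 females gave 1631 for 20 s and 3 for 3 s, the neutrophil enzyme gene Mpo (−2.08 ± 0.32), Hoxa7 (−2.79 ± 0.46) and an unnamed transcript (−2.35 ± 0.39), reported after their values were seen.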

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

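The tests in this part were fixed before the data were examined, and none was chosen after its result was seen. For each group of 9 arrays, or of 4 males or 5 females for genes of the X and Y chromosomes, the gap between the farthest array and its nearest neighbour was divided by the range of the group (Dixon's ratio, tested at the 95% level). Chance exceeds the limit in about 1 in 20 groups, and 19 of 280 ratios did, 4 for sex-linked genes, 15 of 225 for genes chosen by rule and none for measures of whole arrays. The sex-linked genes give 40 groups, but Xist lacked a value in the 20 s males and gave no ratio there. Values are log2 signals relative to each array's 75th percentile, and no cause was tested for single arrays. Uty was well above background on 1 of the 36 arrays, so its values are mostly readings of background.

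Array plasma_3s replicate 7, labelled female, stood apart in 5 genes. It read 3.38 for Idua (ratio 0.698, the others −1.82 to −0.25), 0.75 for Pign (0.681, the others −5.30 to −3.37) and 3.76 for Itgam (0.655, the others −1.55 to 0.28). Against the other 4 females of its group it read −6.12 for the Y-linked gene Uty (0.747, the others −11.51 to −10.15) and −6.75 for Xist (0.857, the others −5.13 to −4.86). Array plasma_20s replicate 6 was the lowest of its group in 5 genes. It read −6.81 for Cd36 (0.497, the others −4.91 to −2.98), −3.41 for Lpl (0.562, the others −1.39 to 0.18) and −8.93 for Fkbp4 (0.698, the others −5.19 to −3.57). It also read −6.23 for Hsph1 (0.581, the others −3.70 to −1.87) and −7.43 for Nfe2l2, the gene of the factor NRF2 (0.667, the others −4.20 to −2.59).

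Among controls, replicate 4 read −1.61 for Thrsp (0.562, the others −7.08 to −4.68), −3.57 for Ces1d (0.591, the others −7.60 to −5.96) and 3.23 for Sbsn (0.531, the others 4.02 to 4.72). Replicate 2, a male, read −7.90 for Loxl1 (0.52604, the others −6.65 to −5.52) and −9.24 for Uty against the other males (0.840, −7.14 to −6.74). Replicate 3 read −6.50 for Mcm3 (0.590, the others −4.81 to −3.64), and replicate 9 read −5.26 for Egr1 (0.720, the others −3.09 to −2.24). Array plasma_20s replicate 1 read −6.70 for Eif2s3y against the other males of its group (0.851, −4.62 to −4.26). Array plasma_3s replicate 2 read −6.11 for Ptprb (0.4996, the others −4.54 to −2.96).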

How the results depend on the processing

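The percentile over all probes, the array signal as a covariate, slide block and array signal together, the arrays without the dimmest slide, and those without the 2 plasma_0s libraries at odds with their sex label were chosen after the data were seen. Under quantile normalization and the percentile over all probes 0 of the genes chosen by rule turned direction, and with each probe on its own every count of genes stayed within 1.5 times. With no term for sex, only the 2 groups compared, the replicate block and the slide block 0 turned direction as well. Each group holds the same number of arrays per labelled sex, replicate number and slide. These settings therefore leave the group differences nearly unchanged and could not reverse them. Of 134 values of such genes 131 kept sign and side of the threshold under quantile normalization, 129 with the percentile over all probes, 130 with array weights, 134 with the slide block and 133 with the replicate block. Under the normexp correction 81 did, 31 fell short of the threshold and 22 reversed, and in the deposited values 115 of 125 did and 2 reversed. With males or females only 43 and 58 did, with the array signal 55, with slide and signal 19, without the dimmest slide 128 and without the 2 plasma_0s libraries 131. Over the fits that left out 1 array each, 2293 of 2412 values did and 0 reversed. Signal over background limits what can be seen, and 42 of the 134 values belong to genes well above background on all 36 arrays.

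With the replicate number as a block, 4370 genes passed for 3 s against control, 5962 for 20 s against control, 6665 for 3 s against 0 s and 7998 for 20 s against 0 s, while limma called 0 for 0 s against control (319 at an unadjusted p under 0.05) and for 20 s against 3 s (177). The lists past camera's test were 25, 25, 16, 14, 11 and 15 in that order. The numbers do not pair the arrays: only 11 of 36 arrays correlated best with an array of their own number, against 26 of 36 with one of their own slide (correlations across genes, which are not independent replicates). The replicate block could not be fitted for female against male, whose numbers do not overlap.

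Leaving out 1 array at a time gave 2039 to 5111 genes for 3 s against control, 3724 to 6796 for 20 s against control, 4361 to 7107 for 3 s against 0 s and 5799 to 8512 for 20 s against 0 s. The lowest counts for 3 s against control were 2039 without plasma_3s replicate 3, 2087 without plasma_3s replicate 4, 2355 without control replicate 3 and 2435 without control replicate 9. Female against male gave 5787 to 7657 genes. For 0 s against control (196 to 379 genes at an unadjusted p under 0.05), 20 s against 3 s and both interactions, limma called 0 to 0.

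The normexp background correction gave 6304 genes for 3 s against control, 12333 for female against male and 20 lists for 3 s against 0 s. It reversed Ttyh3 (−0.048), Kit (−0.26), Mcpt-ps1 (−0.23), Glis2 (−0.14), Lhx2 (−0.039), Abcc4 (−0.54), Fkbp4 (−0.39), Pdgfra (−0.52) and the mast cell list's median (−0.35) for 3 s against control. For 20 s against control it reversed Glis2 (−0.037), Kit (−0.39), Nqo1 (−0.85), Loxl1 (−0.28), Tie1 (−0.81), Mcm3 (−0.12), Fkbp4 (−0.46), Gata2 (−0.40) and the mast cell median (−0.39). Against the 0 s group it reversed Xdh (−0.20), Eif3a (−0.21), Kit (−0.30), Abcc4 (−0.48) and the mast cell median (−0.34) at 3 s, and Glis2 (−0.037), B4galt5 (−0.20) and the mast cell median (−0.43) at 20 s. The mast cell median for 20 s against 3 s became −0.012. The median of all genes was −0.67 and −0.69 for 3 s and 20 s against control there, and the cause was not tested.

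Quantile normalization left 13 lists for 3 s against control, and array weights left 13 lists there and called 2744 and 162 genes in the 3 s and 20 s interactions. In the deposited values 13 lists passed for 3 s against control and 3 for 20 s against 0 s, Soga1 for 3 s against control read −0.21 and Kdr for 20 s against control 0.73. With the slide block 7048, 8343 and 9026 genes passed for 3 s against control, 20 s against control and 3 s against 0 s, and limma called 0 for female against male (1723 at an unadjusted p under 0.05), a fit that rests on the 2 plasma_0s libraries at odds with their labels. For these settings the cause was not tested.

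Without the filter on dim probes more genes were tested, and 17637 (3 s against control), 19416 (20 s against control), 19641 (3 s against 0 s), 21134 (20 s against 0 s) and 14204 (female against male) passed. Most of the calls against control were falls there (2153 higher and 15484 lower, and 3278 and 16138), and the median of all genes was −1.13 and −1.09. With only probes well above background on all 36 arrays fewer genes were tested, and 1593, 1840, 2315, 2489 and 2532 passed in the same order, with 7, 11, 3 and 2 lists for the first 4 comparisons. With fewer arrays, males only gave 8 genes for 3 s against control, 0 for 20 s against control (limma, 3822 at an unadjusted p under 0.05) and 3743 for 20 s against 0 s. Females only gave 3, 1631 and 1296 for these and 148 for 3 s against 0 s. The fits against 0 s use the labels, so the males hold plasma_0s replicate 2 and the females plasma_0s replicate 5, the libraries at odds with their sex label.

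Camera with an estimated correlation called 0 lists in all 6 comparisons (2, 2, 4, 0, 0 and 5 at an unadjusted p under 0.05 for 3 s, 20 s and 0 s against control, 3 s and 20 s against 0 s, and 20 s against 3 s). Fry's directional test called 0 lists for 0 s against control (1 at an unadjusted p under 0.05) and 0 for 20 s against 3 s (0 at an unadjusted p under 0.05). It called 28 for 3 s against 0 s and 32 for 20 s against 0 s. Fry does not compare a list with other genes, and 35.4% and 43.3% of all genes passed in these 2 comparisons. Its counts therefore do not show that the lists stand out. For camera with an estimated correlation the cause was not tested.

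With the array signal as a covariate 43, 231, 1775 and 2173 genes passed for 3 s against control, 20 s against control, 3 s against 0 s and 20 s against 0 s, and 9 and 5 lists for 3 s against control and 20 s against 0 s. With slide block and array signal 0 (limma, 2863 at an unadjusted p under 0.05), 2, 174 and 0 genes (2995) passed in that order, and for 20 s against control Fkbp4 (−0.013) and Hsph1 (−0.037) reversed. Without the dimmest slide 7 lists passed for 20 s against 0 s, and the mast cell median for 20 s against 3 s was −0.12. Without the 2 plasma_0s libraries 7 lists passed for 0 s against control, and the mast cell median there was 0.094. For the covariate settings the cause was not tested, and the last 2 settings use fewer arrays.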

Other observations

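The tests of array signal, of hybridisation or scanning efficiency, of a response separate from the array signal, of receptor genes, of the background floor, of mast cell genes with the array signal as a covariate and of splits within slides were chosen only after the result was seen.

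Several cell types and programmes did not pass as lists in the 20 s group against controls (n = 9 per group). Macrophage genes lay 0.51 above all genes (5 of 22 rose and 0 fell, 3 and 0 adjusted over the list alone; camera's adjusted p = 0.089) and above them in 4 of 5 slides, between −0.33 and 1.07. Genes of Schwann cells, which wrap nerves, lay 0.51 above (4 of 14 rose and 0 fell by either adjustment, adjusted p = 0.17), in 5 of 5 slides. Melanocyte genes lay 0.50 above (4 of 10 rose and 0 fell, 5 and 0 adjusted over the list alone, 0.17). Complement genes lay 0.53 above (5 of 16 rose and 1 fell by either adjustment, 0.14) and cytokine and chemokine genes 0.29 above (6 of 27 rose and 1 fell, 5 and 1 adjusted over the list alone, 0.21). Targets of p53, the factor of the DNA damage response, lay 0.14 above (4 of 29 rose and 0 fell, 1 and 0 adjusted over the list alone, 0.20), and cholesterol synthesis genes 0.29 above (3 of 22 rose and 0 fell, 2 and 0 adjusted over the list alone, 0.082). Interferon response genes lay 0.04 above (3 of 26 rose and 4 fell, 2 and 4 adjusted over the list alone, 0.90) and oxidant-producing enzymes 0.15 above (2 of 12 rose and 2 fell by either adjustment, 1.0), although the test's direction was downward for both.

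Keratinocyte lists other than the cornified envelope did not pass in this comparison either. Basal keratinocyte genes lay 0.23 above all genes (3 of 15 rose and 0 fell, adjusted p = 0.20) and suprabasal genes at −0.25 (4 of 27 rose and 1 fell, 0.42), with 0 genes of either list past the threshold adjusted over the list alone. Hair follicle keratins lay 0.13 above (6 of 50 rose and 1 fell, 4 and 1 adjusted over the list alone, 0.65) and wound keratins and alarmins at −0.13 (3 of 24 rose and 1 fell by either adjustment, 0.79). Muscle genes lay 0.09 above (0 of 49 passed by either adjustment, 0.79, with the test's direction downward) and between −2.06 and 1.43 in single slides. Ribosomal protein genes lay at −0.25 (0 of 48 rose and 2 fell, 0 and 1 adjusted over the list alone, 0.25). Cartilage genes lay at −0.73 (1 of 9 rose and 3 fell by either adjustment, 0.28) and genes of red blood cells at −0.57 (2 of 12 rose and 0 fell, 0 and 0 adjusted over the list alone, 0.40).

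The first pattern is the large number of genes past the threshold in the 3 s and 20 s groups, whose arrays were also the brighter ones. A loss of hybridisation or scanning efficiency on the control arrays would lower the spike-ins too, but within slides the spike-ins differed by −0.36 ± 0.10 and the skin signal by 1.82 ± 0.33 (20 s minus control, SE over 5 slides), a ratio of −0.20 that argues against it, while labelling stays open because the protocol does not say when spike-ins were added. The difference in array signal between groups is a candidate explanation. The slope of each gene on array signal was taken within group and slide among 18 plasma_0s and plasma_3s arrays, of which 16 shared group and slide with another. This slope correlated with the 20 s minus control change at r = 0.80 across 16923 genes, which are not independent replicates. Because treated 3 s arrays enter the slope and their animals may differ in response, it cannot separate array signal from a response. With the signal as a covariate 3.89% of the genes called in the 20 s group passed again, and their median size of change went from 1.29 to 0.75 while the median SE stayed near 0.38, so the calls ended with the smaller change. A response of the skin that is separate from the array signal cannot be told apart from that signal for these genes, because the plasma groups hold the brighter arrays, and an unequal mass of skin RNA relative to spike-ins stays open, untested.

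The second pattern is the large falls of genes with no known use in skin in the 20 s group, such as Fgf23 and Tssk5. Signal at the background floor of dim arrays is argued against for 8 olfactory and vomeronasal receptor genes well above background on all 36 arrays, of which 7 fell, but cannot be told apart for the other 43 (17 fell), none of which was well above background on all arrays. Signal that does not come from the gene's own transcript stays open and may account for part of the falls, since 24 of 51 such receptor genes fell and 0 rose (odds ratio 5.62 against all other genes, Fisher's exact test, two-sided p = 9.9e-09, and 11.4 against other genes with a symbol, p = 1.7e-14). Under the normexp correction 49 fell, under quantile normalization 19 and in the deposited values 23 of 45, with 0 rising in each, and without the filter on dim probes 16138 genes of all kinds fell and 3278 rose. A fall of these transcripts themselves stays open and was not tested.

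The third pattern is the rise of mast cell genes in the 20 s group. The array signal as a covariate left 0.87 of the list's median (1.70 without and 1.47 with it; mean 1.41 ± 0.27 and 1.36 ± 0.32 SE), which argues against the array signal as the whole cause. A lower share of keratinocytes would raise the markers of all other cell types alike, but the mast cell list lay apart from 5 of 6 other lists: mean changes were larger by 0.60 ± 0.15 than for fibroblast, 0.70 ± 0.22 endothelial, 0.82 ± 0.17 macrophage, 0.89 ± 0.27 Schwann cell and 2.03 ± 0.32 T and NK cell genes (SE), and by 1.24 ± 0.66 than for muscle genes, under 2 SE. The medians of these lists were 0.88, 1.06, 0.72, 0.72, −0.58 and 0.30 in that order, so most of them rose as well. A lower share of keratinocytes as a part of the mast cell rise is therefore not excluded. The mast cell list was also picked for its rise, which favours a place above the others. Background correction stays open, since under the normexp correction 1 member, Mcpt4, rose and 1 fell. Of the 10 genes 2 are also on another list and 5 were well above background on under 5 control arrays. The offset of 50 in that correction can itself shrink rises of dim genes and was not varied. The normexp values alone therefore do not show that the rise comes from background. More mast cells, or more RNA of these genes per mast cell, may lie behind the 1.36 ± 0.32 that remained, as a hypothesis, although with the covariate Srgn (−0.050 ± 0.39) and Tpsb2 (0.62 ± 0.54) were not past the threshold, and counts of mast cells in sections, not made here, would be needed to choose between them.

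Each count was compared with those of 100 splits of the same arrays into groups of the same sizes, the real split included. For 20 s against control 1 of 100 gave as many genes (5216, highest other 1291) and 3 of 100 as many lists (24, highest other 25), so chance can be excluded for these counts in these splits. It can be excluded too for the genes of 3 s against control (1 of 100; 3806, highest other 2684), 3 s against 0 s (2 of 100; 5997, highest other 6161) and 20 s against 0 s (1 of 100; 7322, highest other 624). For 20 s against control 1 of 100 gave as large a place of the mast cell list (1.48, highest other 1.12). That list was picked because it rose most in these data, and the splits followed it alone, so this does not exclude chance for it. For female against male 1 of 100 splits gave as many genes (6675, highest other 2859), but the splits do not keep the slides, so this does not exclude the slides, which nearly coincide with sex. Chance cannot be excluded for the lists of 3 s against control (11 of 100; 20, highest other 25), 0 s against control (27; 11, highest other 24), 3 s against 0 s (43; 12, highest other 25), 20 s against 0 s (32; 13, highest other 24) and 20 s against 3 s (22; 14, highest other 24). The other splits passed a median of 10 lists for 3 s and for 20 s against control, and 6 for 0 s against control. They passed 10 and 11 for 3 s and 20 s against 0 s, and 10 for 20 s against 3 s. Camera with the preset correlation thus passes many lists where the groups are mixed, and its adjusted p-values are too small here.

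These splits do not keep the slides, so 100 splits that exchange arrays within slides were drawn as well. As many genes were given by 1 of 100 for 3 s against control (3806, highest other 325), 20 s against control (5216, highest other 5), 3 s against 0 s (5997, highest other 4522) and 20 s against 0 s (7322, highest other 4347), so chance can be excluded. The mast cell list lay as far from all genes in 1 of 100 (1.48, highest other 1.27), which again does not exclude chance for a list picked for its rise. For the lists chance cannot be excluded here, also not for 20 s against control, where the first splits excluded it: 5 of 100 gave as many for 3 s against control (20, highest other 21) and 5 of 100 for 20 s against control (24, highest other 25). It was 22 of 100 for 0 s against control (11, highest other 20), 34 for 3 s against 0 s (12, highest other 22), 35 for 20 s against 0 s (13, highest other 21) and 29 for 20 s against 3 s (14, highest other 23). The other splits within slides passed a median of 9 lists for 3 s and 12 for 20 s against control.

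Where limma called 0 genes, 100 of 100 splits give as many by construction, which says nothing about chance. This holds for 0 s against control (0, highest other 1372), 20 s against 3 s (0, highest other 2095) and the interactions at 3 s/mm² (0, highest other 1219) and 20 s/mm² (0, highest other 1). Unadjusted p under 0.05 was found for 248, 107, 522 and 418 genes in these 4. Splits that called many genes point to a structure of the samples that does not follow the groups. Between the sides of the highest other splits for genes that do not keep the slides, array signal differed by −2.09 log2 units for 3 s against control, 1.71 for 20 s against control, −0.89 for 0 s against control, 1.92 for 3 s against 0 s (1.63 in the real split), 0.80 for 20 s against 0 s, 1.84 for 20 s against 3 s and −1.70 for female against male (1.55 in the real split).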
